A study of Homo sapiens with 44 samples.

How the data were processed

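The data are 1 table of gene expression for 44 RNA-seq libraries of the human lymphoma lines TMD8 and HBL1. Per the labels, libraries were made with standard Illumina protocols after RNA extraction, from total RNA in TMD8 and polyA RNA in HBL1. Per the submitters' processing notes, reads were counted with HTSeq on the hg19 genome. The HTSeq version, its strand setting and the aligner are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be told apart.

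The authors deposited log2 values per gene, described by them as normalized by a median shift, together with the total of mapped reads per library. Checked on the table, each deposited log2 value equals the log2 of the gene's reads times 1 factor per library, and 0 where there were no reads. Values under 20 reads came out as whole reads within 0.05 of a read in 100% of cases in every library, and the recovered reads summed to 99.9825% to 100.018% of the stated total. A single read was worth between 1.18 and 2.55 on the linear scale. Totals ran from 11367575 to 23313660 reads, and a count of 0 allows up to 3 reads. Such limits cover counting error only.

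Tests were run on the deposited log2 values, without a further pseudocount. A gene without reads is held at 0, and so is a library in which it could not have been seen, which limits the falls that can be measured in weakly read genes. Of 25066 genes, the 15040 with a mean at or above the 40th percentile (1.805 on the log2 scale, about 1.72 reads in a library of median depth) were tested. limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend and Benjamini-Hochberg adjustment, and a gene is called at an adjusted p below 0.05. Every adjusted p given for a gene comes from limma. Errors of log2 fold changes are standard errors and errors of group means are standard deviations over cultures.

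The treatment effect was fitted within each line with the knockout genotype as a term and, in HBL1, the library set. The difference between the lines came from 1 fit to all 44 libraries. Controls, TNFAIP3 knockouts and autophagy knockouts were compared within each treatment with the library set as a term, all 3 classes sharing 1 estimate of the spread, and their responses by an interaction. Initiation and later autophagy genes were compared on the mean of each TMD8 culture's 2 libraries. The HBL1 libraries form 2 sets because sample descriptions differ in form and control and TNFAIP3 cultures are numbered R1 and R2. Libraries whose titles share the line, the knockout and any number were taken as 1 culture given both treatments, so genotype pairs most of the libraries. Both orders of ULK1 and ULK2 share 1 genotype term, and so do the HBL1 R1 and R2 cultures of a class, which differ by the set term only. Deviations of the paired libraries correlated with a median of 0.426 (0.0821 to 0.65 over 22 cultures, lowest in the TMD8 control), and 14 of 22 cultures correlated best with their own partner. In HBL1 only the R1 TNFAIP3 culture did not. In TMD8 the control, ATG9A, ULK1 then ULK2, RB1CC1, ATG14, WIPI2 and ATG7 cultures did not, so the pairing by title has less support there. In 160 pairs of libraries of 1 set and treatment, counts differed by a chi-square per gene of 1.61 to 18.7, so none of these pairs appeared to be 1 library deposited again. Pairs across sets or treatments were not compared.

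Of 32 gene lists fixed in advance, 30 had at least 2 tested genes. Lists can share genes, such as JUNB, IL6 and IL10 in the NF-kB and JAK-STAT3 targets, so their results are not independent. The 636 symbols were matched to the table by symbol or, for 18, by gene identifier through the GRCh38.p14 gene table, which was used for names only; 635 matched and 602 were tested. No coordinates are given, since that assembly is not the one the authors used. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. No list that passed changed the sign of its mean after quantile normalization. The lists of other cell types served only to look for foreign RNA: T and NK cell markers reached 11 reads at most, myeloid markers 25, erythroid markers 4 and stromal markers 132, against 53309 for the B-cell marker CD74. The myeloid and stromal lists, with 3 tested genes each, did not pass in the acalabrutinib comparisons (camera adjusted p 0.489 and 0.243 in TMD8, 0.99 and 0.988 in HBL1). In TMD8, though, the stromal genes COL1A1 and DCN were 1.17 and 2.51 log2 units higher with acalabrutinib, and the myeloid gene ITGAM 1.34.

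Genes are named by a rule: in the treatment comparisons the 10 largest changes each way among called genes that moved that way in at least 10 of 11 cultures, and in the class comparisons with DMSO the 10 largest each way among called genes on the same side in all 3 library sets. In the other comparisons the 4 largest called each way are named. Where nothing is called the 4 smallest p-values are given as values. Every target and up to 4 list members with the largest absolute statistic are named too. Clone and LOC names are counted but not named. Exceptions are said to be chosen after their values were seen. The NF-kB score is the mean log2 value of the 40 listed targets, TNFAIP3 among them, per library, tested by exact permutation of the control label within library sets.

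The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives chosen then were no filter, a filter at the 60th percentile (10027 genes), a pseudocount of 3.495, quantile normalization, robust empirical Bayes, a block for each culture, cell line in place of library set, single lines or HBL1 sets, leaving out cultures, and for the NF-kB score z scores and the list without TNFAIP3. Added after seeing the data were voom weights on the recovered reads (the weighted fit, 13032 genes with a mean of at least 10 reads), single-genotype fits, TMD8 without its ULK1 and ULK2 cultures, a limit of 10 mean reads in each line for the difference between lines, a score for the interferon list, and the NF-kB score without targets under 10 mean reads in a line with DMSO.

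The fits were tested on simulated data with 200 genes changed, each by the same fold in every culture of the group concerned. Recovery of 2-fold changes among 15040 genes was 89.6% for acalabrutinib in TMD8, 79.1% in HBL1, 71.6% for the difference between the lines, 62.7% and 52.2% for TNFAIP3 knockouts with DMSO and acalabrutinib, and 71.6% for initiation against later genes. In the difference between the lines 37 of 181 calls were genes without a simulated change, and 32 of these 37 had under 10 mean reads in 1 line. With at least 10 mean reads in each line (11478 simulated genes) it was 5 of 133. For TNFAIP3 knockouts 13 of 138 calls with DMSO and 12 of 120 with acalabrutinib were unchanged genes, and for autophagy knockouts 3 of 141 and 12 of 145. For acalabrutinib it was 11 of 183 in TMD8 and 6 of 162 in HBL1, and for initiation against later genes 11 of 161. The share of false calls can therefore exceed 5%, and not in the small groups alone.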

Results

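RNA was sequenced from TMD8 and HBL1, established human cell lines of the activated B-cell-like type of diffuse large B-cell lymphoma, whose growth depends on signalling from the B-cell receptor (BCR). The cells carried Cas9 knockouts and had been given DMSO or acalabrutinib, an inhibitor of Bruton's tyrosine kinase (BTK), for 24 hours. By their titles, the 44 libraries were taken as 22 cultures, 11 per line, each sequenced under both treatments. There were 3 control knockout cultures, 3 of TNFAIP3 (also called A20, a deubiquitinase that restrains NF-kB signalling) and 16 of autophagy genes. The autophagy targets were ATG101, ATG9A, RB1CC1, ATG14, WIPI2, ATG5 and ATG7, and ULK1 together with ULK2. The HBL1 libraries fell into 2 sets of 5 and 6 cultures, each with its own control and TNFAIP3 culture. The total of mapped reads given for each library in the deposited table ran from 11367575 to 23313660, with a median of 13298953 in TMD8, 19539437.5 in the first HBL1 set and 13658784 in the second. The sample labels give 25 nM acalabrutinib for TMD8 and 100 nM for HBL1, while the protocol text gives 25 nM, so the HBL1 dose rests on the sample label alone. TMD8 RNA is labelled total RNA and HBL1 RNA polyA RNA. Nothing in the labels says that cultures of a class were derived separately, so p-values measure the spread between these cultures. The series title ties the response to BTK inhibitors to selective autophagy, and the comparisons follow from that.

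The targeted transcripts were examined first. Their level was lowest in the knockout libraries themselves in 41 of 46 target and library pairs, against 6.45 pairs if ranks were random. RB1CC1, a scaffold of the ULK complex, lay 1.32 to 1.46 log2 units below the median of the other TMD8 libraries (differences of -1.46 and -1.32 in its 2 libraries). WIPI2, which binds phosphatidylinositol 3-phosphate on forming autophagosomes, had a mean difference of -0.97 in TMD8 and -1.28 in HBL1. ATG7, the E1-like enzyme of the conjugation systems, had -1.10 in TMD8, and ATG5 had -0.72 and -0.56 in the 2 lines. ATG101 (listed under its older symbol C12orf44) had -0.97 in TMD8 and -0.15 in HBL1, and ATG14 (listed as KIAA0831) had -0.34 and -0.45. ULK1 had -0.38 in TMD8 and -0.89 in HBL1, and ULK2 had -0.40 and -0.33. TNFAIP3 had -0.61 in TMD8 and -0.48 in HBL1, with 1 HBL1 library at the median of the others (difference 0). ATG9A differed least in TMD8, by -0.15 on average, with 1 library 0.026 above the median of the others. Cas9 insertions and deletions need not lower a transcript, so these values check the labels and not the loss of protein.

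**Figure D1:**
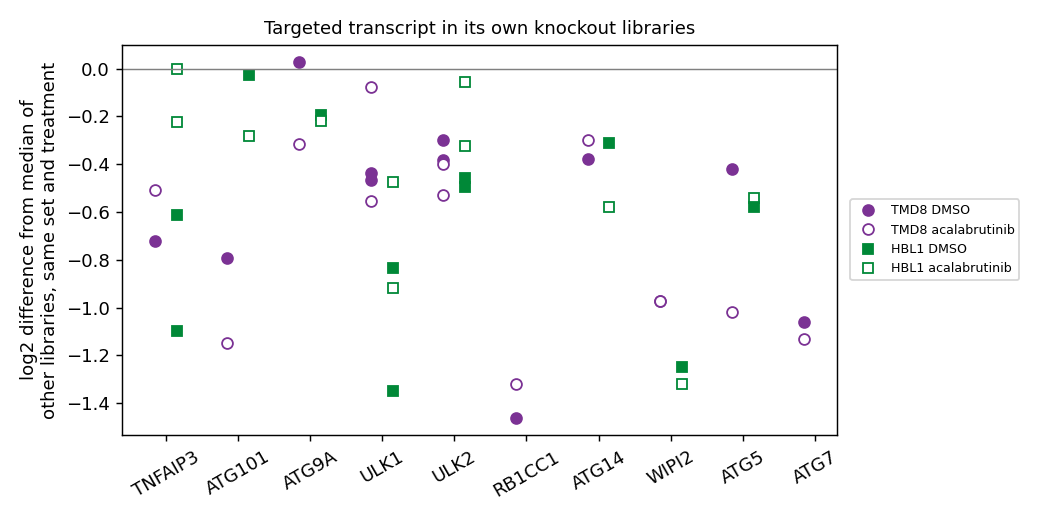
Level of each targeted transcript in its own knockout libraries, as the log2 difference from the median of the other libraries of the same set and treatment. Each point is 1 library, circles are TMD8 and squares HBL1, filled points DMSO and open points acalabrutinib; points below 0 are lower than that median, as for RB1CC1 at -1.46 and -1.32.

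In TMD8, EGR2 (gene identifier 1959), a transcription factor induced by BCR signalling, fell with acalabrutinib by 5.32 ± 0.14 (SE) log2 units, from 11.40 ± 0.52 to 6.09 ± 0.79 (SD, n = 11 cultures), and its relative EGR3 (1960) changed by -5.83 ± 0.22. The chemokines CCL4 and CCL3 changed by -5.89 ± 0.34 and -5.16 ± 0.27, and the cytokines IL17F, IL12B and IL6 by -6.66 ± 0.37, -5.12 ± 0.24 and -4.47 ± 0.28. FOS changed by -4.79 ± 0.29, THRB, a thyroid hormone receptor, by -4.38 ± 0.35 and TPRG1 by -4.25 ± 0.58. IL17F went from a mean of 79 reads to 0.727 and EGR3 from 57.8 to 0.909, so the size of these falls is set by few reads. The largest rises were ELFN2 (4.06 ± 0.36), AFF2 (3.81 ± 0.34) and NLRP7 (3.76 ± 0.25), followed by the gap junction genes GJB2 (3.60 ± 0.21) and GJB6 (3.55 ± 0.31). VPREB3, a protein of the pre-B-cell receptor complex, rose by 3.20 ± 0.15, F2RL3 by 3.18 ± 0.35, the potassium channel gene KCNH2 by 3.16 ± 0.34, PACSIN1 by 3.06 ± 0.16 and TMEM132B by 3.05 ± 0.34. With DMSO the mean reads were 1.55 for AFF2, 2.36 for TMEM132B, 3.18 for ELFN2, 4.18 for GJB2 and 4.64 for F2RL3. The size of these rises is therefore set by few reads too. All 20 named genes moved the same way in 11 of 11 cultures, with limma adjusted p from 9.32e-11 to 5.76e-05. Over all 15040 genes tested, 7705 changed at an adjusted p below 0.05, 4017 up and 3688 down, of which 515 rose and 369 fell by at least 2-fold.

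By gene list, 37 of 40 NF-kB targets fell in TMD8 and 2 rose (37 and 2 adjusted over the list alone). TNF fell by 3.31 ± 0.11, NFKBID, an inhibitor of NF-kB, by 2.38 ± 0.06, the phosphatase gene DUSP2 by 2.37 ± 0.08 and JUNB by 2.24 ± 0.08. Of 20 BCR and ERK early genes 15 fell and 3 rose, and EGR1 fell by 3.66 ± 0.23. These were the 2 lists whose call held with an estimated correlation (adjusted p = 0.0033 and 0.0046). With the preset correlation, 15 of 30 lists passed, and for the other 13 the adjusted p with an estimated correlation lay between 0.192 and 0.575. Among these, 31 of 32 MYC-linked ribosome biogenesis genes fell (POLR1C by 0.46 ± 0.03, adjusted p = 0.192 with an estimated correlation for the list). All 13 heat shock genes fell (HSPA8 by 0.48 ± 0.06, 0.192). In the E2F and DNA replication list 23 of 30 genes fell (GINS2 by 0.42 ± 0.07, 0.436), but E2F2 rose by 1.28 ± 0.08. JAK-STAT3 targets fell in 11 of 17 cases, among them IL10, which is also a listed NF-kB target, by 4.04 ± 0.17 and CD274, which encodes PD-L1, by 1.56 ± 0.06 (0.27). ATF4 targets fell in 15 of 24 cases, ASNS by 0.93 ± 0.09 (0.192). BCR signalling components rose in 16 of 21 cases, CD79B by 1.51 ± 0.09 (0.341), and MHC class II genes in 11 of 14, HLA-DMB by 1.06 ± 0.10 (0.27). Lysosomal genes rose in 18 of 32 cases, CTSB by 0.94 ± 0.08 (0.192), and p53 targets in 14 of 21, CDKN1A by 0.50 ± 0.04 (0.192). FOXO and quiescence targets rose in 12 of 18 cases, MYD88 pathway components in 9 of 17 and replication-dependent histones in 11 of 15 (each 0.192). Type I interferon genes rose in 11 of 26 cases (0.575), and the mean of that list, examined after the data were seen, in 7 of 11 cultures. The autophagy machinery, with 13 of 34 genes up and 5 down, and the selective autophagy receptors, with 6 of 12 up and 2 down, did not pass (camera adjusted p = 0.0885 and 0.342).

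In HBL1, acalabrutinib raised MYADML2 the most, by 4.44 ± 0.29 (SE), from 3.06 ± 1.27 to 7.50 ± 0.54 (SD, n = 11 cultures). MMP11, a matrix metalloproteinase, rose by 3.55 ± 0.27, CEACAM1 by 2.92 ± 0.26, VPREB3 by 2.74 ± 0.18, RCSD1 by 2.49 ± 0.39, NLRP7 by 2.49 ± 0.12 and SUSD3 by 2.48 ± 0.23. RASGRP2, a guanine nucleotide exchange factor, rose by 2.34 ± 0.18, TMC8 by 2.34 ± 0.30 and D4S234E (now NSG1) by 2.27 ± 0.13. The largest falls were the chemokine CCL22 (-2.85 ± 0.25), the retinoid receptor RXRA (-2.63 ± 0.28), the prostaglandin receptor PTGER4 (-2.54 ± 0.20) and LRRC32 (-2.41 ± 0.13). GPRC5B changed by -2.21 ± 0.32, TNFAIP2 by -2.14 ± 0.22, RASGRP1 by -2.13 ± 0.16, ITGA1 by -2.11 ± 0.40, SOCS3, a feedback inhibitor of cytokine signalling, by -2.06 ± 0.19 and CX3CL1 by -1.97 ± 0.54. With DMSO the mean reads were 1.55 for MMP11, 3.91 for CEACAM1, 6.27 for MYADML2, 7.27 for RCSD1 and 8.64 for ITGA1. The size of these changes is therefore set by few reads. Each gene named here moved in its direction in 10 or 11 of 11 cultures, with limma adjusted p from 4.07e-09 to 0.00809. In total 6576 genes changed, 3712 up and 2864 down, with 335 up and 108 down by at least 2-fold. Within the first and the second HBL1 set alone, 4267 and 4318 genes changed, and CX3CL1 missed the threshold in the first (-2.27, adjusted p = 0.0637).

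In HBL1 33 of 40 NF-kB targets fell and 3 rose (34 fell adjusted over the list alone), with TRAF1 at -1.43 ± 0.08, BCL2A1 at -1.49 ± 0.09, IRF4 at -0.98 ± 0.06 and MIRHG2, the host of miR-155, at -1.70 ± 0.11 (adjusted p = 0.0589 with an estimated correlation). With the preset correlation 17 of 30 lists passed. FOXO and quiescence targets held with an estimated correlation (adjusted p = 0.0486): 15 of 18 rose, CCNG2 by 1.60 ± 0.12, TSC22D3 by 1.56 ± 0.13 and BTG2 by 1.15 ± 0.07. MYC-linked ribosome biogenesis genes fell in 31 of 32 cases, POLR1C by 0.48 ± 0.03 (adjusted p = 0.0556 with an estimated correlation). E2F and DNA replication genes fell in 28 of 30 cases, PCNA by 0.40 ± 0.03 (0.0589), and mitosis genes in 9 of 25 (0.51). Lysosomal genes rose in 24 of 32 cases, PSAP by 0.65 ± 0.03 (0.0556), MHC class II genes in 12 of 14, HLA-DMA by 0.77 ± 0.04 (0.0556), and BCR signalling components in 13 of 21, CD79B by 0.81 ± 0.05 (0.0556). Germinal centre B-cell genes rose in 10 of 19 cases (0.137), and oxidative phosphorylation genes in 15 of 30 (0.409). Of 20 BCR and ERK early genes 10 fell, JUN by 1.31 ± 0.19, while TRIB1 rose by 0.95 ± 0.13 (0.322). JAK-STAT3 targets fell in 7 of 17 cases (0.0589), ATF4 targets in 13 of 24 (0.235) and cholesterol synthesis genes in 7 of 23 (0.472). mTORC1-linked genes fell in 10 of 18 cases (0.16) and heat shock genes in 9 of 13 (0.16). Type I interferon genes fell in 16 of 26 cases, IFI44L by 1.16 ± 0.26 (0.586), while STAT2 rose by 0.50 ± 0.04. However, the mean of that list, examined after the data were seen, fell in 5 of 5 cultures of the first set and rose in 3 of 6 of the second (by 0.353, 0.27 and 0.107). The autophagy machinery (14 of 34 up, 5 down) and the selective autophagy receptors (7 of 12 up, 3 down) did not pass here either (camera adjusted p = 0.0917 and 0.174).

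**Figure D2:**
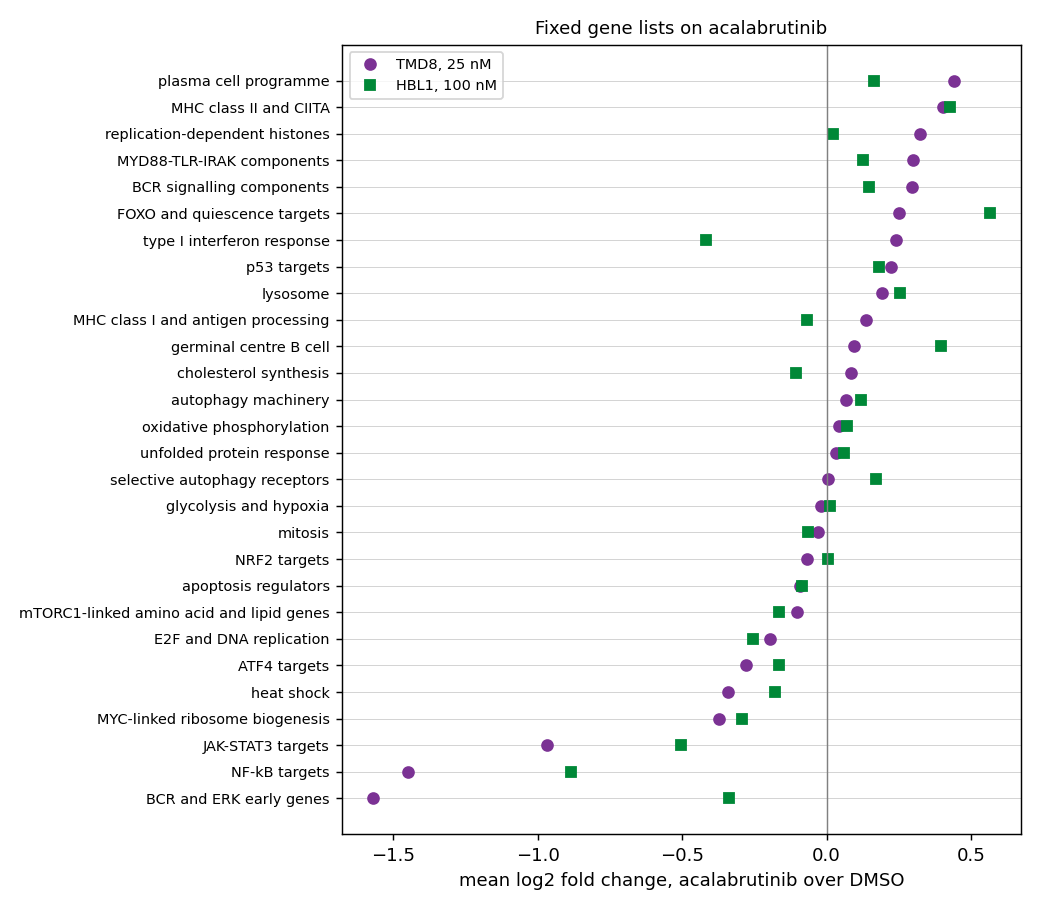
Mean log2 fold change of each gene list fixed in advance except those of other cell types, acalabrutinib over DMSO, in TMD8 (circles, 25 nM) and HBL1 (squares, 100 nM by the sample label), 11 cultures each. Each point is the mean over the list's tested genes, without error bars; the NF-kB targets lie at -1.45 in TMD8 and -0.884 in HBL1, and after quantile normalization NRF2 targets, glycolysis and hypoxia genes and replication-dependent histones change sign in HBL1.

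The mean log2 value over the 40 NF-kB targets fell in every culture of both lines. In TMD8 it went from 11.07 ± 0.14 to 9.62 ± 0.07, a change of -1.45 ± 0.13 (SD, n = 11, 2-sided exact sign-flip permutation p = 0.000977). In HBL1 it went from 10.21 ± 0.17 to 9.33 ± 0.17, a change of -0.88 ± 0.23 (SD, n = 11, exact permutation p = 0.000977). The change was -0.97 ± 0.20 in the first HBL1 set and -0.81 ± 0.24 in the second. The change in HBL1 was smaller by 0.565 log2 units (permutation p = 1e-05, the smallest that 100000 resamples can give). Without IL6 and CXCL10, which had under 10 mean reads in a line with DMSO, the score changed by -1.36 in TMD8 and -0.874 in HBL1, a difference of 0.482 (permutation p = 2e-05), a check added after the data were seen.

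**Figure D3:**
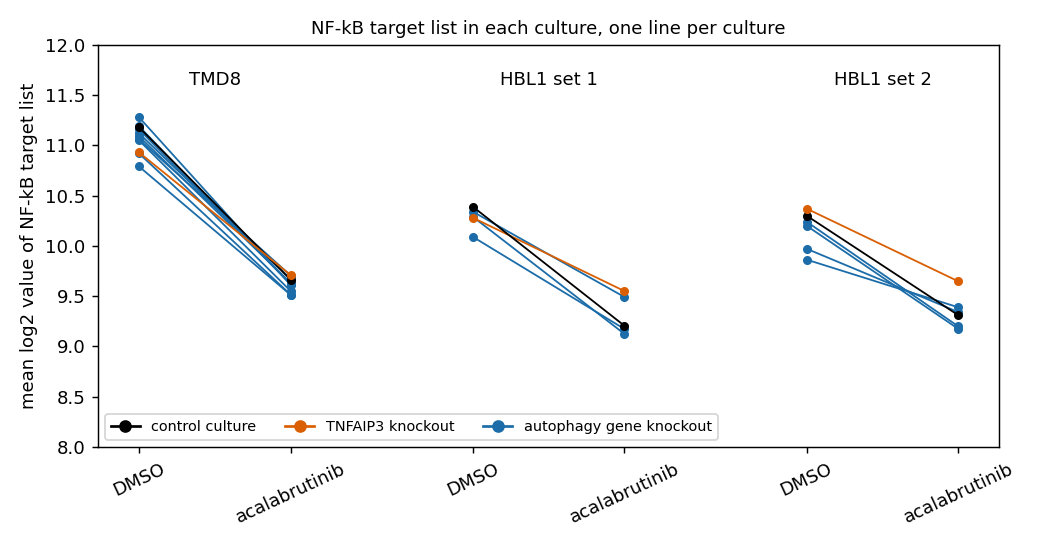
Mean log2 value of the 40 NF-kB target genes with DMSO and with acalabrutinib, 1 line per culture, in TMD8 and in both HBL1 sets (control cultures black, TNFAIP3 knockouts orange, autophagy gene knockouts blue). All 22 lines slope down, from means of 11.07 to 9.62 in TMD8 and 10.21 to 9.33 in HBL1.

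Whether the lines differed in their response was tested directly. EGR2 changed by -5.32 ± 0.49 in TMD8 and 0.50 ± 0.65 in HBL1 (SD, n = 11 each), a difference of 5.82 ± 0.27 (SE, limma adjusted p = 1.7e-15), and EGR3 by -5.83 ± 0.68 and -0.57 ± 0.69 (adjusted p = 1e-12). IRAK3, an inhibitory kinase of the MYD88 pathway, changed by 2.78 ± 0.83 in TMD8 and -0.31 ± 0.79 in HBL1 (adjusted p = 4.09e-07), at a mean of 7.82 reads in the HBL1 DMSO libraries. The other named differences were IL17F (6.57), IL12B (5.03), GJB6 (-3.67), GJB2 (-3.53) and F2RL3 (-3.24). All 5 had a mean of 0.182 reads in the HBL1 DMSO libraries, so their values are the TMD8 change set against a gene close to unread, and no response could be measured in HBL1. In all, 3504 genes differed, 1906 with a higher and 1598 with a lower change in HBL1. Of these, 419 had fewer than 10 mean reads in 1 of the lines, a kind of gene that was also called without a simulated change. Among the 11511 genes with at least 10 mean reads in each line, a limit chosen after the data were seen, 3259 differed, 1774 higher and 1485 lower. Of these, chosen after their values were seen, CCL4 changed by -5.89 in TMD8 and -1.37 in HBL1, CCL3 by -5.16 and -1.03, EGR1 by -3.66 and 0.44, and RGS1 by -1.87 and 1.20. HTR3A changed by 1.74 and -0.98, RXRA by 0.09 and -2.63, CX3CL1 by 0.71 and -1.97, LTBP2 by 2.62 and -0.05, OLFML2A by 2.51 and 0.01, and TNFRSF21 by 1.49 and -0.81. Dose, RNA type and line differ together and cannot be told apart.

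By list, 8 of 30 passed with the preset correlation and 0 with an estimated one. Of 26 type I interferon genes, 18 changed less upward or more downward in HBL1 and 0 the other way (adjusted p = 0.38 with an estimated correlation). Of 20 BCR and ERK early genes, 14 had a higher and 3 a lower change in HBL1 (0.171), and of 40 NF-kB targets 17 and 3, with CD44 at 0.88 ± 0.04 and JUNB at 1.38 ± 0.10 (0.38). FOXO and quiescence targets had 7 higher and 3 lower (0.227). Cholesterol synthesis genes had 1 higher and 13 lower, LSS at -0.51 ± 0.10 (0.38), and MHC class I and antigen processing genes 0 and 8, PSMB8 at -0.39 ± 0.05 (0.227). BCR signalling components had 1 and 7 (0.432) and MYD88 pathway components 1 and 5 (0.216). Much of the response was in the same direction: 2181 genes rose in both lines, where independent lists would share 991.4, 1903 fell in both (702.3 expected) and 333 went opposite ways (1675 expected). Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.482 and rho = 0.516.

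With DMSO, no single gene separated the 16 autophagy knockout cultures from the 3 controls. Among the smallest p-values were those of PSEN2 (1.09 ± 0.28 SE), SMARCA1 (-0.61 ± 0.15) and IGSF3 (-1.26 ± 0.32), each with a limma adjusted p of 0.997. limma called 0 genes at an adjusted p below 0.05, with 706 at an unadjusted p below 0.05, and the weighted fit to reads called 1. Within TMD8 alone, with 1 control culture, 9 genes were called. With acalabrutinib limma called 0 again (589 unadjusted; weighted fit 0), and 13 within TMD8 alone. The smallest p-values were those of TMC4 (-0.68 ± 0.16), CYB5D1 (0.36 ± 0.09), the transcription factor gene POU2F1 (-0.55 ± 0.13) and PPAPDC3, now PLPP7 (-1.41 ± 0.34, 0 to 28 reads), each with an adjusted p of 0.995. In simulated data with these group sizes, 71.6% of 2-fold changes were recovered with DMSO and 68.7% with acalabrutinib. The simulated change was the same in all 16 cultures, so this says nothing of effects of single knockouts.

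Gene lists moved by small amounts. With DMSO, 36 of 40 NF-kB targets lay lower in the autophagy knockouts, none of them called, with NFKBIA at -0.30 ± 0.10 and NFKBIE at -0.27 ± 0.09 (camera adjusted p = 1.28e-07, or 0.345 with an estimated correlation). The NF-kB score of these cultures was 0.164 lower than in controls of the same set (2-sided exact permutation p = 0.075 over 200 arrangements, adjusted p = 0.428 over 6 tests), or -0.312 as z scores, with an unadjusted p of 0.04. With acalabrutinib the difference was -0.0123 (exact permutation p = 0.855), with a sign that changed under other settings. Of 26 type I interferon genes 25 lay lower in the knockouts under either treatment (preset adjusted p = 2.33e-14 and 5.22e-09, but adjusted p = 0.345 and 0.588 with an estimated correlation). The mean over that list, tested after this was seen, differed by -0.507 with DMSO (exact permutation p = 0.09), made up of -0.169 in TMD8, 0.0953 in the first HBL1 set and -1.45 in the second, where the control culture stood at 11.27 and the other cultures between 9.459 and 10.04. NRF2 targets lay higher in 18 of 23 cases under either treatment (adjusted p = 0.345 and 0.506 with an estimated correlation), and oxidative phosphorylation genes in 26 of 30 with DMSO (0.345). Glycolysis and hypoxia genes lay higher in 22 of 28 cases with DMSO (0.697) and 23 of 28 with acalabrutinib (0.588). In all 8 lists passed with DMSO and 11 with acalabrutinib under the preset correlation, and 0 under an estimated one.

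In the TNFAIP3 knockouts with DMSO, ADK (gene identifier 132), adenosine kinase, was 0.43 ± 0.07 (SE) log2 units higher than in controls (11.18 ± 0.33 against 10.75 ± 0.24, SD, n = 3 each, 1.35-fold). It was higher in all 3 library sets, with a limma adjusted p of 0.0499. limma called 2 genes, with 2065 at an unadjusted p below 0.05. No call held without the first or the second HBL1 control culture, without the TNFAIP3 culture of the first HBL1 set, without a filter, with a pseudocount or with cell line in place of library set (0 genes each), while 128 genes were called without the TMD8 control and 203 without the TMD8 TNFAIP3 culture. The weighted fit to reads called 301. With acalabrutinib limma called 0 genes (1528 unadjusted; weighted fit 13). The smallest p-values were those of EPHX2, an epoxide hydrolase (-1.15 ± 0.19, adjusted p = 0.0568), DRAM, now DRAM1, a lysosomal p53 target linked to autophagy (1.45 ± 0.27, 0.0922), the lipoxygenase gene ALOX15 (-3.22 ± 0.67, 0.256) and MAPKAPK2 (-0.58 ± 0.12, 0.256). Without the TMD8 TNFAIP3 culture 3 genes were called with acalabrutinib, and without the TMD8 control 1.

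Among the lists, MYC-linked ribosome biogenesis genes lay higher in the TNFAIP3 knockouts in 26 of 32 cases with DMSO and 32 of 32 with acalabrutinib (adjusted p = 0.904 and 0.454 with an estimated correlation). With acalabrutinib 28 of 40 NF-kB targets lay higher (0.454), as did 29 of 30 E2F and DNA replication genes (0.57) and 10 of 13 heat shock genes (0.454). BCR signalling components lay lower in 18 of 21 cases under both treatments (0.666 and 0.57). Type I interferon genes lay lower in 24 of 26 cases with DMSO and 25 of 26 with acalabrutinib (0.904 and 0.57), with differences of the list mean with DMSO of 0.241 in TMD8, -0.042 in the first HBL1 set and -1.81 in the second, whose control culture stood apart. Glycolysis and hypoxia genes lay lower in 23 of 28 cases with DMSO (0.904). With DMSO NFKBID was at -0.86 ± 0.21 and REL at -0.57 ± 0.15, neither called. In all 7 lists passed with DMSO and 14 with acalabrutinib under the preset correlation, and 0 under an estimated one. The NF-kB score of TNFAIP3 knockouts differed from controls by -0.0946 with DMSO (exact permutation p = 0.5) and 0.242 with acalabrutinib (exact permutation p = 0.25), where 3 pairs cannot give a p below 0.25.

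The change on acalabrutinib was then compared between classes. Between autophagy knockouts and controls the smallest p-values were those of ABCB9, a lysosomal peptide transporter (1.29 ± 0.31), GADD45A, a stress-induced gene (2.06 ± 0.51, 0 to 116 reads), DPH2 (0.23 ± 0.06) and CDKL1 (-0.81 ± 0.23), each with an adjusted p of 1. limma called 0 genes (543 unadjusted; weighted fit 0), and 10 within TMD8 alone. Between TNFAIP3 knockouts and controls they were ZBTB44 (-0.40 ± 0.09), DAPP1, an adaptor in BCR signalling (-0.38 ± 0.09), the myosin gene MYO1C (0.48 ± 0.11) and FHL3 (0.95 ± 0.23), each with an adjusted p of 0.78. Here limma called 0 genes as well (798 unadjusted; weighted fit 0), and 12 within TMD8 alone. The estimated fall of NF-kB targets was smaller than in controls for 34 of 40, none called, in each kind of knockout (adjusted p = 0.497 for autophagy and 0.161 for TNFAIP3 with an estimated correlation). Both use the same 3 control cultures, so this agreement is no separate evidence. On the score the change was 0.152 smaller in autophagy knockouts (exact permutation p = 0.285) and 0.337 smaller in TNFAIP3 knockouts (exact permutation p = 0.25, the smallest possible). The autophagy score differed from controls by -0.164 with DMSO and -0.0123 with acalabrutinib, and the TNFAIP3 score by -0.0946 and 0.242. None of these differences passed (adjusted exact permutation p of 0.428 or more). It therefore cannot be said under which treatment the smaller changes arose. The autophagy value with acalabrutinib also changed sign under other settings. In controls CCL22 fell by 3.24 ± 1.10 and in TNFAIP3 knockouts by 1.79 ± 1.03 (SD, n = 3 each, limma adjusted p = 0.78). For MYC-linked ribosome biogenesis the estimates lay on the side of a smaller fall for 27 of 32 genes in autophagy knockouts (0.575) and 31 of 32 in TNFAIP3 knockouts (0.445), again with none called. In all 6 and 8 lists passed under the preset correlation and 0 under an estimated one.

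Autophagy and TNFAIP3 knockouts were also compared directly with DMSO. BEST4 (266675), a chloride channel gene read 1 to 28 times per library, was 2.29 ± 0.32 (SE) higher in autophagy knockouts (4.49 ± 0.50 in 16 cultures against 2.23 ± 1.00 in 3, limma adjusted p = 0.00668). ZNF575 (284346), a zinc finger gene, was 1.10 ± 0.19 higher and PFKL (5211), liver-type phosphofructokinase, 0.48 ± 0.08 higher (adjusted p = 0.0293 each). These were the 3 genes called, with 1982 at an unadjusted p below 0.05 and 59 by the weighted fit. The count was 0 without either HBL1 TNFAIP3 culture, with the filter at the 60th percentile and with cell line in place of library set, and 139 without the TMD8 TNFAIP3 culture. With an estimated correlation 0 of the 8 lists called remained, among them glycolysis and hypoxia (higher in autophagy knockouts in 27 of 28 cases, adjusted p = 0.642). The autophagy and TNFAIP3 comparisons share their controls. They shared 0 calls at an adjusted p of 0.05 and at 0.2, as they had to with 0 autophagy calls at either, where TNFAIP3 had 404 higher and 359 lower at 0.2. Their log2 fold changes had a covariance of 0.0776, against a mean of 0.0644 (0.0612 to 0.0694) in 100 simulations of unchanged groups with the same controls, a difference of 0.0132. Their r of 0.646 lay inside the simulated range (0.623 to 0.663, mean 0.64), so the measures disagree. The simulation drew each gene independently, while genes of a control culture can deviate together, as interferon genes did in the second HBL1 control. Its ranges may therefore be too narrow to judge either measure. With 3 controls these could not be divided, so part of the excess in covariance may come from the shared controls.

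Within TMD8, 5 cultures with knockouts of initiation genes (ATG101, ATG9A, RB1CC1 and both orders of ULK1 and ULK2) were set against 4 of later genes (ATG14, WIPI2, ATG5, ATG7). limma called 2 genes, with 1924 at an unadjusted p below 0.05. PAIP2B had 0 or 1 read per TMD8 library and gives no fold, and the other is a locus without a gene name. Without the ATG14 culture 662 genes were called, and the count was 0 without ATG101, ATG9A, ULK1 then ULK2, RB1CC1, WIPI2, ATG5 or ATG7. Replication-dependent histones lay lower in the initiation knockouts in 13 of 15 cases, the 1 list called (adjusted p = 0.56 with an estimated correlation).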

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

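The weighing of whether genotype sets the response size or the likeness to TNFAIP3 loss, of the genes with few reads in HBL1, and of HBL1 sets with genes chosen in the other set, used tests chosen after the result was seen. The other tests were chosen before their results.

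The response to acalabrutinib differed between HBL1 and TMD8 in 3504 genes by the interaction test, and in the named genes EGR2 (5.82 log2 units higher change in HBL1), EGR3 (5.26) and IRAK3 (-3.09). IL17F (6.57), IL12B (5.03), GJB6 (-3.67), GJB2 (-3.53) and F2RL3 (-3.24) were called too, but with a mean of 0.182 reads each in the HBL1 DMSO libraries no response could be measured there. The change of the NF-kB score differed by 0.565. Of the genes that fell in TMD8, 1333 fell less or rose in HBL1, of which 385 were called lower and 189 higher in HBL1 itself.

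For these 1333 genes a level too low in HBL1 cannot be the whole cause, since 9% had 10 or fewer mean reads in the HBL1 DMSO libraries. For those 120 genes, however, a different response cannot be told apart from a low level, because genes of that kind were called in simulated data without a change. That at least 99.9% of the 1333 genes fell less than in TMD8 in each HBL1 set follows from their choice. Of genes chosen in 1 HBL1 set and some TMD8 cultures, at least 89.5% fell less in the other set than in the remaining TMD8 cultures (single TMD8 cultures at most 85.2%, the lowest HBL1 culture 66.8%), which argues against a single HBL1 set as the whole cause. The line itself, the 100 nM against 25 nM dose and polyA against total RNA stay open as untested explanations. Among 100 reassignments of cultures to lines no other gave as many genes (3504, highest other 1). Groups that mix the lines leave the line difference in the spread, which lowers their counts. The reassignments therefore do not measure how many of the 3504 calls are false, and in simulated data 37 of 181 such calls were unchanged genes.

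ZNF575 stood out in the RB1CC1 knockout of TMD8 with DMSO, at 4.65 where the other autophagy knockouts lay between 5.41 and 5.73. CYB5D1 stood out in the ULK2 then ULK1 knockout of the second HBL1 set with acalabrutinib, at 8.8 where the others lay between 9.01 and 9.02. These were 2 of 59 groups examined, where chance gives 2.95.

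The size of the acalabrutinib response, measured by projecting each culture on the mean response of the other line, was smaller than in the control in TMD8 for ATG9A (difference -0.52), TNFAIP3 (-0.444), ATG14 (-0.334) and ATG101 (-0.321), and in HBL1 by -0.169, -0.0259, -0.122 and -0.16. WIPI2 differed by -0.184 in TMD8 and -0.149 in HBL1, ATG5 by -0.138 and -0.0183, and ULK1 with ULK2 by 0.0326 and 0.033. Apart from ULK1 with ULK2, each TMD8 value is 1 culture. All TMD8 values share 1 control, whose paired libraries correlated least (0.0821). Each HBL1 set has its own single control. A deviation of a control shifts all differences taken from it. Over 7 genotypes the differences from control correlated between the lines with r = 0.601 (exact permutation p = 0.154, adjusted p = 0.304 over 6 correlations) and rho = 0.679 (p = 0.11), and r was -0.0445 without 2 genotypes, so the relation rests on these. The authors' scaling stays open: r was 0.533 after quantile normalization (p = 0.203; -0.261 without 2 genotypes), and a relation that passed no threshold cannot be said to be kept. Library depth may contribute: response size and total reads over 11 TMD8 cultures had rho = 0.327 (permutation p = 0.329) and r = 0.174 (p = 0.607; 0.632 without 2 cultures). Whether genotype sets the response size stays open.

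Autophagy knockouts with DMSO were projected on the TNFAIP3 profile of the other library sets, giving 0.149 for ATG9A, 0.117 for ATG14, 0.0952 for ATG101, 0.0942 for WIPI2, 0.0527 for ULK1 with ULK2 and 0.043 for ATG5 in HBL1, and 0.0262, 0.0215, 0.0192, -0.0138, -0.00438 and -0.0375 in TMD8. The TNFAIP3 knockouts themselves had 0.234 and 0.221 in HBL1 but 0.0241 in TMD8, below 0.075 for RB1CC1, so in TMD8 the projection hardly registers TNFAIP3 loss. Over these 6 genotypes the lines correlated with r = 0.826 (exact permutation p = 0.0514, adjusted p = 0.154) and rho = 0.943 (p = 0.0167), with r = 0.935 without 2 genotypes. Library depth had rho = 0.103 (permutation p = 0.705) and r = 0.0563 within library sets (-0.0591 without 2 cultures), too few cultures to exclude it. After 269 genes linked to proliferation were removed r was 0.826 (p = 0.0486, rho = 0.714, 0.539 without 2 genotypes), which leaves proliferation open too, as the relation had not passed before. That the genotype sets how much of the TNFAIP3 profile is shared stays open at these p-values and with such TMD8 values. The HBL1 genotypes come from 2 sets, each measured against 1 control culture, whose own deviation shifts all of its projections.

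Other groupings of the same cultures were fitted for the remaining counts. For acalabrutinib in TMD8 and HBL1 (7705 and 6576 genes), no other of 100 exchanges of treatment within cultures gave as many, with highest others of 6067 and 3741, each from an exchange in 1 culture (ATG101 in TMD8 and the R1 TNFAIP3 culture in HBL1). For autophagy knockouts against controls with DMSO (0 genes, highest other 25), with acalabrutinib (0, highest other 16) and in their response (0, highest other 0), all 100 of 100 groupings give as many because none can give fewer, so they decide nothing. The TNFAIP3 comparisons allow only 4 groupings, too few for a share under 0.05, with 2, 0 and 0 genes for DMSO, acalabrutinib and the response and highest others of 0, 0 and 1. For autophagy against TNFAIP3 knockouts 3 of 100 groupings, the real one among them, gave at least 3 genes, and 1 gave 10. That share is under 0.05 but was not adjusted over the comparisons. The count also fell to 0 without either HBL1 TNFAIP3 culture, so chance cannot be excluded for these 3 genes. For initiation against later genes 2 of 100 gave at least 2 genes, and the other, ULK1 with ULK2 in both orders, WIPI2, ATG5 and ATG7 against the rest, gave 1856. The named cultures had acalabrutinib response sizes of 0.675 to 0.915, and the rest 0.34 to 0.649. As this grouping was picked after its count was seen, what divides these cultures was not tested.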

How the results depend on the processing

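The weighted fit, the 10-read limit and the fit without ULK cultures were chosen after seeing the data. Of 974 checks of genes named for acalabrutinib and the line difference, 973 kept direction and side of the threshold, 1 missed it (CX3CL1, first HBL1 set) and 0 reversed. These genes were chosen for the largest changes in the same data, so few checks could fail, and the other calls were not covered. They include IL17F, IL12B, GJB6, GJB2 and F2RL3, for which no response could be measured in HBL1. Leaving out cultures gave 7010 to 7860 genes in TMD8, 6003 to 6628 in HBL1 and 3088 to 3935 for the difference. Without ULK1 and ULK2 cultures TMD8 had 6465, and with 10 reads in each line the difference had 3259. HBL1 set 1 gave 4267 and set 2 4318, with fewer cultures. Quantile normalization moved the share of rises from 52.1% to 48.5% in TMD8 and 56.4% to 47.7% in HBL1. The replicate block gave 7535, 6692 and 3451 genes for TMD8, HBL1 and the difference, and 0 for both class responses. For the counts below the cause was not tested.

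Autophagy knockouts with DMSO: 1 without a filter, 9 in TMD8 only, 1 by the weighted fit, 0 to 1 leaving out controls. With acalabrutinib: 3 without a filter, 13 in TMD8 only, 0 leaving out controls. Their response: 1 without a filter, 10 in TMD8 only. TNFAIP3 with DMSO: 0 without a filter, with a pseudocount or with no replicate block (line in place of set), 12 at the 60th percentile, 20 in TMD8 only, 1 in HBL1 only, 301 by the weighted fit, 0 to 203 leaving out cultures. TNFAIP3 with acalabrutinib: 5 without a filter, 1 at the 60th percentile, with robust empirical Bayes or in HBL1 only, 25 in TMD8 only, 13 by the weighted fit, 0 to 3 leaving out cultures. Its response: 1 without a filter, 12 in TMD8 only. Autophagy against TNFAIP3: 9 without a filter, 0 at the 60th percentile or with no replicate block, 16 in TMD8 only, 1 in HBL1 only, 59 by the weighted fit, 0 to 139 leaving out cultures. Initiation against later genes: 0 with a pseudocount, 0 to 662 leaving out cultures.

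With an estimated correlation, list calls went from 103 to 3: 15 to 2 in TMD8, 17 to 1 in HBL1, and to 0 from 8 for the difference, 8, 11 and 6 for autophagy (DMSO, acalabrutinib, response), 7, 14 and 8 for TNFAIP3, 8 between them and 1 for initiation. The NF-kB score of autophagy knockouts with DMSO had an unadjusted p below 0.05 as z scores only (-0.312, exact permutation p = 0.04) and was -0.193 to -0.129 leaving out controls. With acalabrutinib it reversed to 0.0045 as z scores, 0.00587 after quantile normalization and 0.0119 in HBL1 only, and was -0.0471 to 0.0119 leaving out controls. Depth limits genes under about 3 reads.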

Other observations

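The single-genotype tests here were added after the data were seen, with library set and genotype as terms among the 22 libraries of a treatment, and genotypes with 1 or 2 cultures take their spread from the others. With acalabrutinib the ATG9A knockouts (2 cultures) differed from controls in 113 genes, 17 higher and 96 lower, where the weighted fit called 395. ELL2, an elongation factor of the plasma cell programme, was 1.96 ± 0.27 (SE) higher (limma adjusted p = 0.00862), the transferrin receptor gene TFRC 1.49 ± 0.24 higher (0.0203), RASGRP1 1.55 ± 0.34 higher (0.0459), and CAMP changed by -2.86 ± 0.61 (0.0449). With DMSO the same cultures differed in 0 genes (1188 at an unadjusted p below 0.05, 54 by the weighted fit). The 2 treatments were fitted separately, so whether the ATG9A difference depends on treatment was not tested.

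The TNFAIP3 knockouts differed in 58 genes with acalabrutinib (15 higher, 43 lower, weighted fit 373) and 26 with DMSO (5 and 21, weighted fit 306) when each genotype had its own term. ELL2 was 1.90 ± 0.24 higher with acalabrutinib (adjusted p = 0.00474) and 1.46 ± 0.27 with DMSO (0.0471), LGALS3, galectin-3, 1.05 ± 0.18 higher with acalabrutinib (0.0209), and NCF1, a subunit of the NADPH oxidase, changed by -0.77 ± 0.12 with DMSO (0.0325) and PRKCB, which acts downstream of BTK, by -0.82 ± 0.15 (0.0467). In ATG101 knockouts with DMSO ZFP36L1 changed by -1.02 ± 0.15 (0.0284). RB1CC1 was among 3 genes called in its own knockout with DMSO (-1.44 ± 0.09), WIPI2 was the 1 gene in its own (-1.11 ± 0.09) and ATG7 was among 3 in its own (-1.12 ± 0.15). ULK1 with ULK2 and ATG5 had 0 calls under either treatment, with 630, 352, 753 and 782 genes at an unadjusted p below 0.05 (DMSO first) and 3, 0, 3 and 0 by the weighted fit.

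The first principal component held 80.3% of the variance between libraries and separated TMD8 (total RNA) from HBL1 (polyA RNA), with 3.7% on the second.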
